A study of Mus musculus with 8 samples.

How the data were processed

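Gene expression was measured by RNA sequencing of whole mouse liver in 8 libraries from 4 groups of 2: wild type untreated, wild type given LPS, ApoE-Cyp7a1 transgenic untreated and ApoE-Cyp7a1 transgenic given LPS. LPS is bacterial lipopolysaccharide, an endotoxin. Both libraries of a group were described by the authors as biological replicates. Per the labels the mice were male, and RNA from frozen, pulverized liver was made into libraries with a stranded mRNA kit from Illumina.

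The deposited table holds values in FPKM, a fragment density scaled by transcript length and by mapped fragments, computed by the authors, with 1 column per library and 1 row per gene name. The processing notes of the authors name TopHat2 version 2.1.0, Bowtie2 version 2.2.6, Cufflinks, Cuffdiff version 2.2.1 and the mouse genome build mm10. The gene annotation, read trimming, filters and any scaling between libraries are not given in the sources used here. Fragment counts were not used here, so tests on counts were not run, the depth of each library is unknown, and no counting interval is attached to any value. The lowest values above 0 were checked for a shared step between libraries (values under 0.03 FPKM, ratios within 0.05 on the log2 scale). Of such ratios to replicate 1 of the wild-type LPS group, 63.6% fell in 1 peak for replicate 1 of untreated wild type, 47.8% for replicate 2 of wild type with LPS and 54.4% for replicate 1 of transgenic with LPS, at relative depths of 1.04, 1.17 and 1.03. In the other 4 libraries 10.7% to 26.3% did, and no relative depth was read from them.

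The table has 24545 rows, of which 6197 are 0 in all 8 libraries. All 8 columns matched a sample, with 0 left unmatched. A total of 494 names occur more than once, and for these the copy with the higher sum over the libraries was kept, which dropped 303 value sets. The names of 27 rows had been turned into dates and were kept as unnamed features. Some names share identical values in all libraries, in 563 sets that cover 1300 names. Each set was treated as 1 feature under its joined names, and it counted in a gene list only if all of its names, unnamed gene models and small RNAs aside, were in that list. This left 17294 features with a value above 0. The genes Alb and Slc51a were listed at 0 in all 8 libraries and were not read as absent from liver.

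Values were transformed as log2(FPKM + 1). Features with at least 1 FPKM in at least 2 of the 8 libraries, groups ignored, were tested, which left 11463. A linear model with 1 mean per group was fitted to all 8 libraries in limma version 3.58.1 under R version 4.3.3, with 4 residual degrees of freedom and empirical Bayes moderation along the mean-variance trend (median prior degrees of freedom 3.59). The 5 contrasts were LPS against untreated in each genotype, transgenic against wild type in each treatment, and the interaction, which is the LPS change in transgenic mice minus that in wild-type mice. Tests were 2-sided, and features passed at a Benjamini-Hochberg adjusted p under 0.05. Changes are given on the log2 scale with their SE, and levels in FPKM with the SD of 2 libraries.

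A total of 29 gene lists with 686 entries were fixed before the data were examined, as were the tests, the main alternatives and the rule for named genes. Of these entries, 7 had no value in the table. The lists cover inflammatory programs, the cell types of liver and blood, neighbouring tissues, bile acid, sterol, lipid, glucose and drug metabolism, stress responses, the cell cycle, the clock and sex-biased liver genes. The 28 lists with at least 5 tested features were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists. The companion test was fry, whose p is given unadjusted, and camera with a correlation estimated from the residuals was an alternative. Within a list, counts of genes are given over all genes tested and adjusted over the list alone. Agreement of contrasts across genes was described with Pearson r and Spearman rho, with no p because genes are not independent replicates.

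Genes were named by a rule. It took Cyp7a1 and Apoe, then in each contrast the 10 largest rises and 10 largest falls among genes that passed with both libraries of a group above both of the other (not required for the interaction), and up to 4 members per list, namely the largest changes that passed or, where none did, the 2 with the highest mean. Where no gene passed in a contrast, the 5 with the smallest p were taken. Unnamed gene models, immunoglobulin segments, globins and major urinary protein genes were counted but not named among the largest changes. The rule gave 200 features, and 9 more, chosen after their values were seen, are marked as such. Positions were taken from the GENCODE vM21 annotation, whose build GRCm38 is the same assembly as mm10, by exact gene name, or by the current name for Emr1 and Igj, for 195 of the 209 features.

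Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, median-of-ratios scaling, robust moderation, only the 2 groups compared, the replicate number as a block, an estimated correlation in camera and leaving out each library in turn. Added after seeing the data were leaving out 76 features that follow the pancreatic enzyme genes (Pearson r above 0.9), leaving out both untreated libraries numbered 1, and counting a shared row in a list by any of its names. Where a library was left out, the lone library of its group was assumed to vary like the other groups. Replicate numbers are not stated to pair animals, so the block was used only as an alternative. The steps were tested on simulated data of the same size, in which 200 of 11463 genes were changed, 50 at each size. For the untreated transgene contrast, 1, 28, 50 and 50 of the 50 genes changed by 0.5, 1, 2 and 3 on the log2 scale were recovered, with 9 false calls. For the interaction these numbers were 0, 11, 42 and 47, with 15 false calls. A list shifted by 1 on the log2 scale in the wild-type LPS contrast was called by camera with an adjusted p of 6.12e-26 (0.0231 with an estimated correlation), and camera called 0 of the other lists. The simulated genes varied independently of each other. The simulation therefore cannot show how often camera calls a list whose genes vary together. Each simulated gene also had 1 spread shared by all 4 groups. In the data the SD of log2 differences between replicates ran from 0.233 to 0.484 over the groups, so the recovered numbers need not hold there. For the untreated transgene contrast, 0 of 23 cholesterol synthesis genes passed at a median difference of 2.80. Tables and plots were made in Python version 3.11.15 with pandas version 2.3.3, numpy version 2.4.6, scipy version 1.17.1 and matplotlib version 3.10.9.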

Results

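The data set describes whole liver from 4 groups of 2 mice each, wild type or ApoE-Cyp7a1 transgenic, untreated or injected with LPS every day at 1.5 mg/kg over 7 days. Cyp7a1 is the rate-limiting enzyme of bile acid synthesis. The FPKM of all rows summed to 500765 to 580051 in the 4 untreated libraries and to 406668 to 469644 in the 4 LPS libraries. The 10 highest rows held 15.5% to 16.7% of that sum in untreated libraries and 12.8% to 13.9% in LPS libraries. Between 10927 and 11979 rows per library reached 1 FPKM. The spread between the replicates of a group, as the SD of their log2 differences over the tested genes, was 0.484 in wild type untreated, 0.233 in wild type with LPS, 0.314 in transgenic untreated and 0.467 in transgenic with LPS.

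The Cyp7a1 row, whose gene lies on chromosome 4 from 6265612 to 6275633, was measured at 37.0 ± 17.1 FPKM in untreated wild-type liver (SD, n = 2) and at 71.6 ± 9.78 FPKM in untreated transgenic liver. With LPS it was measured at 23.9 ± 5.67 FPKM in wild type and 71.8 ± 2.29 FPKM in transgenic liver. All 4 transgenic libraries, at 64.7, 78.5, 73.5 and 70.2 FPKM, lay above all 4 wild-type libraries, which held 24.9, 49.1, 19.9 and 27.9 FPKM. Over all genes tested the genotype difference did not pass in either treatment, with log2 differences of 1.00 (SE 0.31, adjusted p = 0.68) in untreated mice and 1.57 (SE 0.31, adjusted p = 0.275) with LPS. The LPS change of Cyp7a1 was -0.55 in wild type (adjusted p = 0.24) and 0.01 in transgenic mice (adjusted p = 0.984), and neither passed. The species of the transgene, and whether its reads are counted in this row beside those of the mouse gene, are not given in the sources used here. The transgenic values may therefore not be a measure of the mouse gene alone. Apoe, on chromosome 7 from 19696109 to 19699188, differed by -0.16 in untreated mice (adjusted p = 1) and by -0.63 with LPS (adjusted p = 0.501).

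The first comparison asked what repeated LPS did to the liver of wild-type mice. Most measured genes of macrophages, neutrophils, plasma cells and extracellular matrix rose, while 9 of 29 fatty acid oxidation, 6 of 16 bile acid synthesis and 7 of 23 drug metabolism genes fell. Marco, a scavenger receptor of macrophages on chromosome 1 from 120474538 to 120505024, rose from 5.65 ± 5.75 to 415 ± 38.2 FPKM (SD, n = 2), a log2 change of 6.30 (SE 0.60, adjusted p = 0.000361). The acute phase genes Saa2 (chromosome 7, 46751790 to 46754313) and Saa1 (chromosome 7, 46740497 to 46742980) rose by 5.96 (SE 0.74) and 4.60 (SE 0.52), to 2637 ± 152 and 2950 ± 304 FPKM. The genes S100a8 and S100a9, which encode the calprotectin subunits of neutrophils, rose by 4.47 and 4.57, and the B cell chemokine Cxcl13 rose by 4.43. In all, 2481 of 11463 genes passed in limma, 1861 higher and 620 lower, and 1059 of the rises and 81 of the falls were at least 2-fold. Of the genes that passed, 75.01% were higher. With quantile normalization this share was 59.5%.

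Macrophage and Kupffer cell genes were the group with the largest rise among lists of more than 20 genes. Of its 23 measured members 20 rose (22 adjusted over the list alone) and 3 did not pass, with a median log2 change of 2.57 (camera adjusted p = 1.01e-14). With an estimated correlation the adjusted p = 0.236. Emr1, which encodes the macrophage marker F4/80, rose by 4.28, Cd5l by 3.72 and the row shared by Lyz1 and Lyz2 by 3.69. All 11 neutrophil genes rose (11 adjusted over the list alone), among them Ngp by 4.15 and Camp by 3.55, with a median of 2.73 (adjusted p = 5.49e-10 by camera, adjusted p = 0.236 with an estimated correlation). All 10 B and plasma cell genes rose, with a median of 1.64, led by Igj, the joining chain of polymeric antibodies, at 4.12 and Mzb1 at 3.20 (adjusted p = 1.43e-08 by camera, adjusted p = 0.236 with an estimated correlation). All 7 red blood cell genes rose as well, by a median of 2.30, with Slc4a1 at 2.75 (adjusted p = 4.27e-06 by camera, adjusted p = 0.259 with an estimated correlation). Only 4 genes of the T and NK cell list reached the filter, so that list was not tested.

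Of 34 stellate cell and matrix genes 30 rose (30 adjusted over the list alone), by a median of 1.31 (adjusted p = 4.82e-15 by camera, adjusted p = 0.236 with an estimated correlation). The fibrillar collagens Col3a1 and Col1a1 rose by 3.56 and 3.16, and Vim, the intermediate filament of mesenchymal cells, by 2.84. Of 19 liver endothelial genes 15 rose, by a median of 1.24, including Cdh5 by 1.84 and Lyve1 by 1.80 (adjusted p = 1.73e-08 by camera, adjusted p = 0.236 with an estimated correlation). Of 27 cell cycle genes 21 rose and 1 fell, with Ccnb2 at 2.05 and Ccna2 at 1.94, both under 5 FPKM in every group mean (adjusted p = 1.24e-10 by camera, adjusted p = 0.236 with an estimated correlation). With the filter of 5 FPKM the cell cycle list had an adjusted p = 0.15 and was not called. Of 25 cytokine, chemokine and NF-kB target genes 16 rose (19 adjusted over the list alone), including Ccl5 by 2.43 and the LPS co-receptor gene Cd14 by 2.42 (adjusted p = 1.29e-07 by camera, adjusted p = 0.236 with an estimated correlation). Of 20 lysosome and lipid-laden macrophage genes 6 rose, with Lgals3 at 2.24 (adjusted p = 0.00734 by camera, adjusted p = 0.289 with an estimated correlation). Of 26 acute phase genes 6 rose and 2 fell, and the list did not pass (adjusted p = 0.197), while Saa1, Saa2, Saa3 and Lcn2 led its rises.

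Of 29 PPARalpha targets and fatty acid oxidation genes 9 fell (17 adjusted over the list alone) and none rose, with a median of -0.64 (adjusted p = 1.05e-07 by camera, adjusted p = 0.236 with an estimated correlation). Cyp4a10, a fatty acid hydroxylase on chromosome 4 from 115518264 to 115533649, fell from 1887 ± 84.7 to 499 ± 156 FPKM (SD, n = 2), a log2 change of -1.95 (SE 0.25, adjusted p = 0.00117), and Vnn1 and Ehhadh fell by 1.80 and 1.50 on the log2 scale. Of 16 bile acid synthesis genes other than Cyp7a1, 6 fell (11 adjusted over the list alone), with a median of -0.61 (adjusted p = 2.43e-05 by camera, adjusted p = 0.236 with an estimated correlation). Among them Cyp39a1, an oxysterol hydroxylase, changed by -1.73, Cyp27a1 by -1.17 and the sterol 12-alpha-hydroxylase Cyp8b1 by -1.06. Of 18 bile acid and sterol transport genes 3 fell and 1 rose, and the bile salt export pump Abcb11 changed by -1.08 (adjusted p = 0.0316 by camera, adjusted p = 0.289 with an estimated correlation). Of 23 cytochrome P450 and drug metabolism genes 7 fell, including Cyp2c37 by 1.60 on the log2 scale (adjusted p = 0.000285 by camera, adjusted p = 0.399 with an estimated correlation). Of 21 NRF2 target and conjugation genes 7 fell and 2 rose, and the largest change in that list was a rise, by 3.13, of the heme oxygenase gene Hmox1 (adjusted p = 0.000571 by camera, adjusted p = 0.289 with an estimated correlation). Of 24 unfolded protein response genes 11 fell and 1 rose, with the chaperone gene Hspa5 at -1.29 (adjusted p = 6.34e-05 by camera, adjusted p = 0.236 with an estimated correlation).

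Of 23 hepatocyte genes 2 fell (Hnf4a by 0.96 and Hpd by 0.92 on the log2 scale) and 1 rose (Trf by 0.98), with a list median of -0.34 (adjusted p = 0.0102 by camera, adjusted p = 0.276 with an estimated correlation). Of 15 male-biased genes 3 fell, led by the fatty acid elongase Elovl3 at -2.08 (adjusted p = 0.000638 by camera, adjusted p = 0.472 with an estimated correlation). Among the lists that camera called for LPS in wild type, the unadjusted p by fry was 0.0591 for drug metabolism and 0.124 for male-biased genes. For the others it was under 0.05. The lists that did not pass were lipogenesis (5 of 22 fell and 2 rose, adjusted p = 0.0649), lipoprotein transport (1 rose and 1 fell of 19, adjusted p = 0.1), glucose metabolism (2 rose and 1 fell of 21, adjusted p = 0.172), female-biased liver (1 of 9 fell, adjusted p = 0.0732), and interferon-stimulated (4 rose and 1 fell of 24, adjusted p = 0.681). Also not past it were cholangiocyte (1 rose and 1 fell of 10, adjusted p = 0.382), immediate early and heat shock (3 of 18 fell, adjusted p = 0.329), circadian clock (1 of 19 fell, adjusted p = 0.388), cholesterol synthesis (0 of 23 in limma by adjusted p, adjusted p = 0.645) and pancreas and adipose (0 of 18 in limma by adjusted p, adjusted p = 0.0761). In the whole contrast 4097 genes had an unadjusted p under 0.05. Within the lipogenesis list, Acacb fell by 1.37 on the log2 scale and the fatty acid transporter gene Cd36 rose by 1.52.

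The count of 2481 was 1219 without replicate 1 and 1337 without replicate 2 of wild type with LPS, and 1379 with the filter of 5 FPKM. The 620 falls were 62 and 64 without these libraries, 1221 and 373 without replicate 1 and replicate 2 of untreated wild type, and 313 and 308 without replicate 1 and replicate 2 of untreated transgenic mice.

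Of the 96 named genes that passed in wild type, 62 kept their call in every refit without 1 library. Without replicate 2 of untreated wild type or either library of wild type with LPS the calls ended for Elovl3 (refit range -2.48 to -1.67), Cyp8b1 (-1.34 to -0.78), Hpd (-0.999 to -0.84) and Trf (0.77 to 1.20), the last also without either untreated transgenic library. Hnf4a lost its call without either library of wild type with LPS (-1.16 to -0.76). Quantile normalization ended the calls of Cyp8b1 and Hpd, no filter that of Trf, and leaving out both untreated libraries numbered 1 those of Hpd, Trf and Hnf4a. For LPS in wild type the transport list had an adjusted p of 0.0715, 0.0501 and 0.0511 without replicate 1 of untreated wild type, replicate 2 of untreated wild type and replicate 1 of wild type with LPS. The hepatocyte list had 0.0886 without the first of these. The male-biased list had 0.0709 without the second. With the filter of 5 FPKM, with quantile normalization and without both untreated libraries numbered 1, the transport list had 0.06, 0.299 and 0.09, and the hepatocyte list 0.0646, 0.927 and 0.116.

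**Figure D1:**
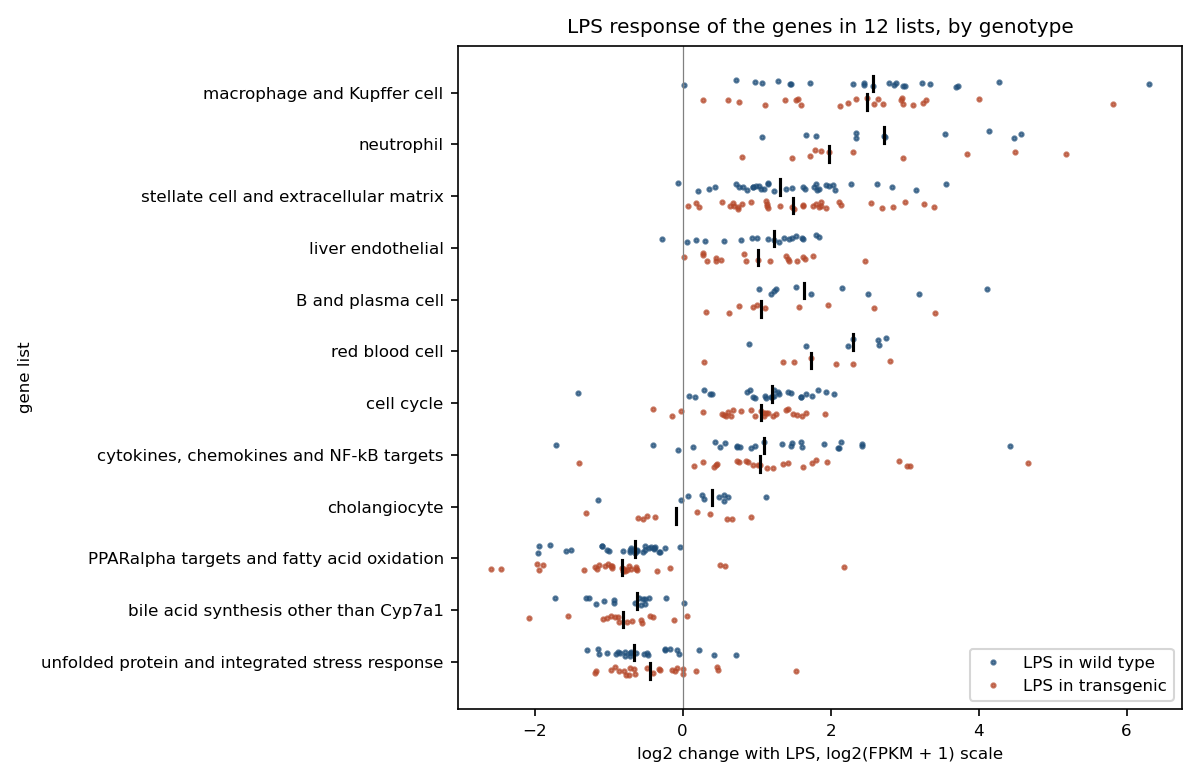
Log2 change with LPS of each measured gene in 12 of the gene lists, for wild-type mice (blue) and transgenic mice (orange), with the list median as a black tick. The macrophage list has medians of 2.57 and 2.49.

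The second comparison asked what the same LPS course did in ApoE-Cyp7a1 transgenic mice. The 10 largest rises held acute phase, macrophage and neutrophil genes, the chemokine gene Cxcl13 (4.67) and the stress response gene Ddit4 (4.54). The largest falls among named genes were in genes of the pancreas, among them Cela2a, Pnlip and Prss2. Of the metabolic lists, 21 of 29 fatty acid oxidation and 10 of 16 bile acid synthesis genes fell. Saa2 rose from 33.6 ± 13.9 to 3712 ± 2662 FPKM (SD, n = 2), a log2 change of 6.59 (SE 0.74, adjusted p = 0.000855), and Saa1 rose by 5.19. Marco rose from 5.84 ± 3.29 to 360 ± 16.6 FPKM, a change of 5.81, S100a8 rose by 5.18 and Cd207, which encodes the lectin langerin, by 4.41. In all, 3034 of 11463 genes passed in limma, 1834 higher and 1200 lower, of which 992 and 344 changed at least 2-fold. The share of higher genes was 60.4%, and 53.8% with quantile normalization.

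Of 23 macrophage genes 21 rose (21 adjusted over the list alone), with Emr1 at 4.00 and the integrin gene Itgam at 3.29 (adjusted p = 1.48e-14 by camera, adjusted p = 0.253 with an estimated correlation). All 11 neutrophil genes rose, by a median of 1.97 (adjusted p = 4.39e-09 by camera, adjusted p = 0.253 with an estimated correlation), as did 9 of 10 B and plasma cell genes, with Igj at 3.42 (adjusted p = 2.53e-06 by camera, adjusted p = 0.253 with an estimated correlation). Of 34 matrix genes 30 rose (31 adjusted over the list alone), among them Col3a1 by 3.39, Col1a1 by 3.26 and the growth factor gene Ctgf by 2.85 (adjusted p = 9.87e-16 by camera, adjusted p = 0.253 with an estimated correlation). Of 19 endothelial genes 13 rose, with Lyve1 at 2.46 (adjusted p = 6.17e-09 by camera, adjusted p = 0.253 with an estimated correlation). Of 27 cell cycle genes 19 rose, including Top2a by 1.67 (adjusted p = 1.64e-09 by camera, adjusted p = 0.253 with an estimated correlation). Of 25 cytokine and NF-kB target genes 17 rose, with Ccl5 at 3.07 and the adhesion molecule gene Vcam1 at 3.03 (adjusted p = 6.17e-09 by camera, adjusted p = 0.253 with an estimated correlation). Of 7 red blood cell genes 6 rose (adjusted p = 6.48e-05 by camera, adjusted p = 0.309 with an estimated correlation), and of 20 lysosome genes 11 rose (adjusted p = 0.000411 by camera, adjusted p = 0.253 with an estimated correlation). Of 26 acute phase genes 9 rose and 1 fell (adjusted p = 0.000322 by camera, adjusted p = 0.341 with an estimated correlation).

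Of 29 PPARalpha target genes 21 fell (22 adjusted over the list alone) and none rose (adjusted p = 3.28e-08 by camera, adjusted p = 0.253 with an estimated correlation). Fabp1, the fatty acid binding protein of liver, fell by 2.45 on the log2 scale, from 7034 ± 671 to 1383 ± 718 FPKM (SD, n = 2), and the hormone gene Fgf21 fell by 2.59 on the log2 scale. Of 16 bile acid synthesis genes 10 fell, with Hsd3b7 at -1.55 and Hsd17b4 at -1.02 (adjusted p = 7.96e-05 by camera, adjusted p = 0.253 with an estimated correlation). Of 18 transport genes 8 fell and 2 rose, with Abcb11 at -1.20 (adjusted p = 0.00434 by camera, adjusted p = 0.253 with an estimated correlation). Of 21 NRF2 target genes 13 fell and 2 rose. The glutathione synthesis gene Gclc changed by -2.08 and Hmox1 by 3.37 (adjusted p = 0.00327 by camera, adjusted p = 0.344 with an estimated correlation). Of 23 drug metabolism genes 9 fell and 2 rose, with Cyp1a2 at -1.82 (adjusted p = 0.00836 by camera, adjusted p = 0.494 with an estimated correlation). Of 15 male-biased genes 8 fell, with Elovl3 at -3.31 (adjusted p = 6.66e-06 by camera, adjusted p = 0.344 with an estimated correlation), and of 24 unfolded protein response genes 11 fell and 1 rose, with Hyou1 at -1.18 (adjusted p = 0.00276 by camera, adjusted p = 0.294 with an estimated correlation). Of 22 lipogenesis genes 6 fell and 2 rose, with Cd36 at 1.68 (adjusted p = 0.0326 by camera, adjusted p = 0.459 with an estimated correlation).

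Of 21 glucose metabolism genes 7 rose, among them Pkm by 2.31 and Igfbp1, a fasting-responsive binding protein gene, by 3.68 (adjusted p = 0.0203 by camera, adjusted p = 0.309 with an estimated correlation). Ddit4 was measured at 6.25 ± 2.44 FPKM in untreated transgenic liver and 192 ± 146 FPKM with LPS (SD, n = 2), with 295 FPKM in replicate 1 and 89.3 FPKM in replicate 2. Igfbp1 stood at 3961 FPKM in replicate 1 and 364 FPKM in replicate 2 of transgenic with LPS, and its call ended without either untreated transgenic library (refit range 1.96 to 5.40). It also ended with no filter, robust moderation or only the 2 groups compared, and without both untreated libraries numbered 1. The cholesterol synthesis list had a median of -1.20 (adjusted p = 0.000424 by camera, adjusted p = 0.505 with an estimated correlation), while 0 of its 23 genes passed in limma, where 4534 of all genes had an unadjusted p under 0.05. Of 18 pancreas and adipose genes 12 fell and 1 rose (adjusted p = 0.00276 by camera, adjusted p = 0.494 with an estimated correlation). Among the lists that camera called for LPS in transgenic mice, the unadjusted p by fry was 0.063 for drug metabolism and 0.0848 for lipogenesis. It was 0.16 for pancreas and adipose and 0.189 for cholesterol synthesis, and under 0.05 for the others. Ctrb1, a digestive protease gene of the pancreas on chromosome 8 from 111686519 to 111691010, changed by -6.04 (SE 1.79, adjusted p = 0.0431), from 786 ± 784 to 19.2 ± 26.0 FPKM (SD, n = 2), and the lipase gene Pnlip changed by -6.07. Both calls ended without replicate 1 of untreated transgenic or replicate 2 of transgenic with LPS (refit ranges -8.23 to -3.85 and -7.46 to -4.68). Both also ended with robust moderation and without both untreated libraries numbered 1. That of Ctrb1 also ended with no filter, and without replicate 2 of untreated transgenic or either library of wild type with LPS.

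The lists that did not pass for LPS in transgenic mice were hepatocyte (3 fell and 1 rose of 23, adjusted p = 0.237), female-biased (4 rose and 1 fell of 9, adjusted p = 0.128), interferon-stimulated (7 fell and 2 rose of 24, adjusted p = 0.124) and immediate early and heat shock (5 rose and 2 fell of 18, adjusted p = 0.486). Also not past the test were lipoprotein transport (3 fell and 1 rose of 19, adjusted p = 0.124), circadian clock (1 rose and 1 fell of 19, adjusted p = 0.317) and cholangiocyte (2 fell and 1 rose of 10, adjusted p = 0.618). Among female-biased genes the transcription factor gene Cux2 rose from 0.209 ± 0.168 to 6.74 ± 3.69 FPKM (SD, n = 2). The count of 3034 was 1501 and 1233 without replicate 1 and replicate 2 of untreated transgenic and 1598 without replicate 1 of transgenic with LPS. It was 1835 with the filter of 5 FPKM and 1669 without both untreated libraries numbered 1. The 1200 falls were 237, 224 and 382 without those 3 libraries. They were 617 and 616 without replicate 1 and replicate 2 of wild type with LPS. The 1834 rises were 1009 and 1216 without replicate 2 of untreated transgenic and replicate 1 of transgenic with LPS. Without the latter the cholesterol, drug metabolism and lipogenesis lists had an adjusted p of 0.125, 0.119 and 0.34. Lipogenesis also lost its call without replicate 1 of untreated transgenic (adjusted p = 0.0524), with the filter of 5 FPKM (0.122), with quantile normalization (0.205) and without both untreated libraries numbered 1 (0.0603). Drug metabolism had 0.0742 with quantile normalization.

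Between the genotypes the LPS changes were correlated across the 11463 genes, which are not independent replicates, with Pearson r = 0.747 and Spearman rho = 0.638. Both contrasts use separate libraries. A total of 1473 genes rose in both genotypes, against 298 for independent calls, 301 fell in both, against 64.9, and 13 changed in opposite directions. The calls of both contrasts share 1 variance per gene from the same fit, which can by itself raise these overlaps above those for independent calls.

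**Figure D2:**
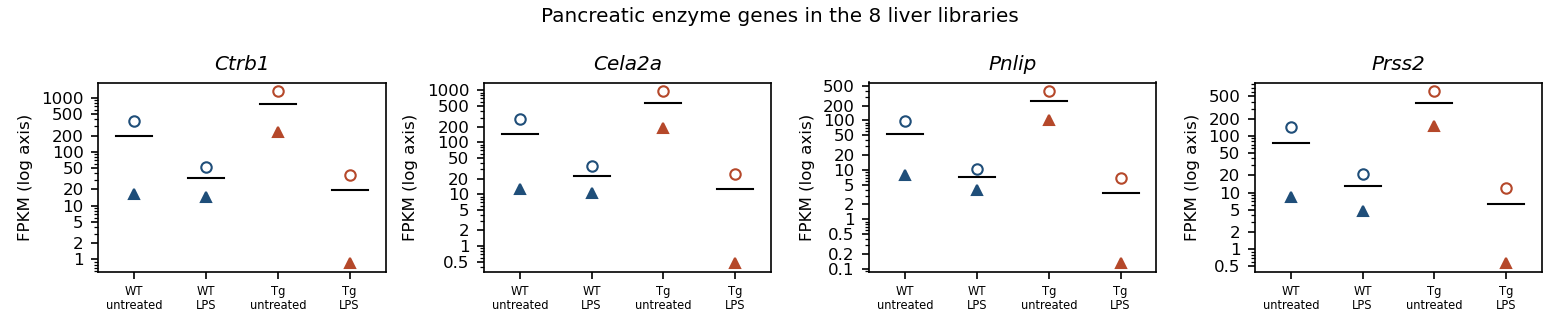
FPKM of pancreatic enzyme genes in each library on a log axis, with wild type in blue, transgenic in orange-red, replicate 1 as an open circle, replicate 2 as a filled triangle and the group mean as a black bar. Ctrb1 lay between 0.860 and 1340 FPKM over the 8 libraries.

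The third comparison asked how untreated transgenic liver differed from untreated wild-type liver. Upp2 and Sult1e1 fell. Genes of cholesterol synthesis had higher values as a group (adjusted p = 1.57e-37 by camera, adjusted p = 0.302 with an estimated correlation), though 0 of 23 passed singly in limma. Upp2, a uridine phosphorylase on chromosome 2 from 58567298 to 58792971, was measured at 297 ± 22.5 FPKM in wild type and 57.8 ± 0.584 FPKM in transgenic liver (SD, n = 2), a log2 change of -2.34 (SE 0.18, adjusted p = 0.00938). Sult1e1, the estrogen sulfotransferase on chromosome 5 from 87575969 to 87591594, changed by -2.11 (adjusted p = 0.0241) and Cyp2c38, on chromosome 19 from 39389556 to 39463075, by -1.39 (adjusted p = 0.0485). The row shared by Kansl2, Mir1291 and Snora34 rose by 2.42 (adjusted p = 0.0107). Snhg9, on chromosome 17 from 24719531 to 24719965, was measured at 1.61 ± 0.431 FPKM in wild type, was listed at 0 in both transgenic libraries (adjusted p = 0.0373). Also past the test were 2 major urinary protein genes chosen after their values were seen. Mup12, on chromosome 4 from 60737383 to 60741326, and Mup8 were listed at 0 in both wild-type libraries and stood at 64.0 ± 36.6 and 3.61 ± 1.32 FPKM in transgenic liver (adjusted p = 0.00938 and 0.0221). With no counts used here, a listed 0 of Snhg9, Mup12 or Mup8 was not read as absence or as a low level, and these 3 calls rest on it.

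In total 7 genes passed, 3 higher and 4 lower, and 631 of 11463 had an unadjusted p under 0.05. That is little above the share of 0.05 that would fall there if no gene differed. The count was 2 without either library of wild type with LPS, 3 and 4 without replicate 1 and replicate 2 of untreated transgenic, and 44 without either library of transgenic with LPS. It was 22 with only the 2 groups compared, of which 2, Upp2 and Mup12, were among the 7. The other 5 lost their calls in that setting, and Cyp2c38 and Snhg9 also lost theirs with the replicate block, Snhg9 with the filter of 5 FPKM and Mup8 with a pseudocount of 0.1. The count was 0 with no filter or without both untreated libraries numbered 1. Mup12 kept its call in all 8 refits without 1 library. Calls ended without either untreated transgenic library for Upp2 (refit range -2.42 to -2.26), Sult1e1 (-2.41 to -1.81), Cyp2c38 (-1.57 to -1.21) and Snhg9. Without either library of wild type with LPS they ended for all of the 7 but Upp2 and Mup12. They ended for Cyp2c38, Snhg9, Mup8 and the Kansl2 row (2.13 to 2.72) when replicate 1 of untreated wild type was left out. Without replicate 2 of untreated wild type they ended for Mup8 and the Kansl2 row.

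All 23 cholesterol synthesis genes had positive log2 differences, with a median of 2.80. None passed over all genes in limma (0 of 23), the smallest adjusted p being 0.111, while 21 were higher adjusted over the list alone. Genes chosen after their values were seen show the size. Hmgcs1, the cytosolic HMG-CoA synthase on chromosome 13 from 119690379 to 119708260, was measured at 17.6 ± 0.626 FPKM in wild type and 352 ± 22.4 FPKM in transgenic liver (SD, n = 2), a difference of 4.24 (SE 0.88, adjusted p = 0.322). Sqle, the squalene epoxidase on chromosome 15 from 59315077 to 59331192, was measured at 3.13 ± 0.491 and 114 ± 17.4 FPKM, which is a difference of 4.80 (SE 0.67, adjusted p = 0.115). These SE pool the spread of all 4 groups, including transgenic with LPS, which is outside this comparison. There Hmgcs1 and Sqle were at 146 ± 172 and 60.2 ± 60.9 FPKM, so the SE are wider than the untreated replicates alone would give. With only the 2 groups compared 13 of the 23 genes passed, and without replicate 1 or replicate 2 of transgenic with LPS 19 passed in each case.

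**Figure D3:**
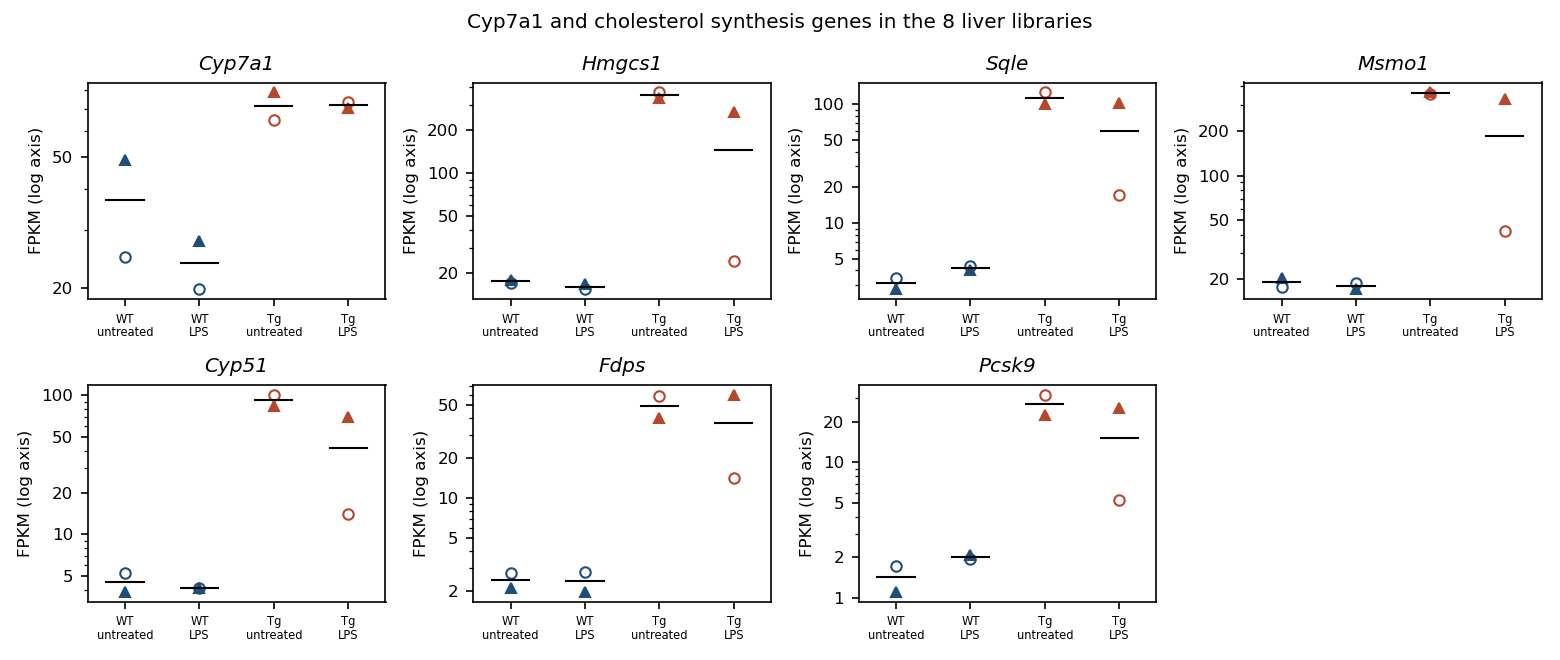
FPKM of Cyp7a1 and cholesterol synthesis genes in each library on a log axis, with wild type in blue, transgenic in orange-red, replicate 1 as an open circle, replicate 2 as a filled triangle and the group mean as a black bar. Hmgcs1 stood at 24.6 FPKM in replicate 1 and 268 FPKM in replicate 2 of transgenic with LPS.

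In untreated mice camera called 13 lists for the transgene, and the other 15 lists had adjusted p from 0.0821 (macrophage) to 0.897 (endothelial). Higher were B and plasma cell (median 0.29, adjusted p = 8.42e-05), interferon-stimulated (0.20, adjusted p = 3.88e-05), cholangiocyte (0.21, adjusted p = 0.037), lipogenesis (0.25, adjusted p = 0.0378) and pancreas and adipose genes (2.55, adjusted p = 0.0173). Lower were drug metabolism (-0.41, adjusted p = 1.68e-05), glucose metabolism (-0.33, adjusted p = 1.67e-05), acute phase (-0.32, adjusted p = 2.42e-05), hepatocyte (-0.20, adjusted p = 0.00022), female-biased (-0.51, adjusted p = 0.000449), bile acid synthesis (-0.16, adjusted p = 0.00178) and NRF2 target genes (-0.20, adjusted p = 0.00258). Each of these 12 calls was lost with an estimated correlation (adjusted p = 0.302 to 0.791 with an estimated correlation). Drug metabolism, with Cyp2c38 as its 1 gene past the test, and glucose metabolism kept their camera calls under every other setting. By fry the unadjusted p was 0.018 for cholesterol synthesis, 0.0294 for female-biased, 0.0391 for glucose metabolism and 0.0427 for hepatocyte genes. For the other lists called it lay between 0.056 (B and plasma cell) and 0.547 (pancreas and adipose), with 0.177 for drug metabolism. Leaving out replicate 1 of untreated wild type, the acute phase, B cell, cholangiocyte, female-biased, hepatocyte, lipogenesis and NRF2 lists had adjusted p of 0.0987, 0.0516, 0.294, 0.0555, 0.114, 0.154 and 0.134. Without replicate 2 of untreated wild type the bile acid synthesis, cholangiocyte, interferon, lipogenesis and pancreas lists had 0.148, 0.113, 0.0635, 0.118 and 0.215. Without replicate 1 of untreated transgenic the cholangiocyte, interferon, lipogenesis and pancreas lists had 0.0775, 0.0775, 0.171 and 0.443. Quantile normalization ended the calls of the bile acid synthesis, hepatocyte and cholangiocyte lists (0.141, 0.141 and 0.0607). A pseudocount of 0.1 ended those of the cholangiocyte and pancreas lists (0.0513 and 0.0544), no filter those of the cholangiocyte and lipogenesis lists (0.139 and 0.0603), and the replicate block that of lipogenesis (0.0506). With both untreated libraries numbered 1 left out, the B cell, NRF2, hepatocyte, cholangiocyte and lipogenesis lists had 0.148, 0.126, 0.059, 0.376 and 0.376. Ctrb1, a pancreatic gene, stood at 381 and 16.3 FPKM in the untreated wild-type libraries and at 1340 and 231 FPKM in the untreated transgenic libraries.

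The fourth comparison asked how transgenic liver differed from wild-type liver under LPS. No gene passed in limma (0 of 11463), and 1402 had an unadjusted p under 0.05. The smallest p belonged to Snhg9 (-1.53, adjusted p = 0.106), the adenosine receptor gene Adora1 (-1.25, adjusted p = 0.11), the acetyl-CoA carboxylase gene Acacb (1.53, adjusted p = 0.11), Slc22a7 (-1.94, adjusted p = 0.192) and Zap70 (-1.67, adjusted p = 0.198). The count was 21 without replicate 1 and 423 without replicate 2 of transgenic with LPS. It was 2 without either untreated wild-type library, 1 without replicate 2 of wild type with LPS, and 1 with no filter or with quantile normalization. The cholesterol list had a median of 1.67, with 22 of 23 genes positive, 12 higher adjusted over the list alone and 0 over all genes (adjusted p = 5.13e-14 by camera, adjusted p = 0.819 with an estimated correlation). Without replicate 1 of transgenic with LPS its median was 2.56 and 14 genes passed, and without replicate 2 it was 0.62 and 7 genes passed. Hmgcs1 differed by 2.27 (adjusted p = 0.379) and Sqle by 3.06 (adjusted p = 0.282).

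Beside the cholesterol list, camera called 8 lists for the transgene under LPS, each of which lost its call with an estimated correlation (adjusted p = 0.706 to 0.819 with an estimated correlation). Higher were glucose metabolism (median 0.22, adjusted p = 0.0104), female-biased (0.38, adjusted p = 0.0104), immediate early and heat shock (0.39, adjusted p = 0.0154) and unfolded protein response genes (0.14, adjusted p = 0.0153). Lower were NRF2 target (-0.39, adjusted p = 0.0153), drug metabolism (-0.47, adjusted p = 0.0221), bile acid synthesis (-0.29, adjusted p = 0.0358) and neutrophil genes (-0.38, adjusted p = 0.0408). By fry the unadjusted p was 0.0243 for female-biased genes and 0.0658 (NRF2 target) to 0.523 (immediate early) for the rest of the 8. For the cholesterol list it was 0.0881. The other 19 lists had adjusted p from 0.0807 (B and plasma cell) to 0.714 (macrophage). Of the 8, glucose metabolism kept its call in every refit without 1 library. Without replicate 1 of transgenic with LPS the immediate early, NRF2, drug metabolism and bile acid synthesis lists had adjusted p of 0.817, 0.12, 0.678 and 0.536. Without replicate 2 of that group the female-biased, unfolded protein and neutrophil lists had 0.0592, 0.145 and 0.942. The neutrophil list had 0.762 without replicate 1 of wild type with LPS. Without replicate 1 and replicate 2 of untreated wild type the bile acid synthesis list had 0.0832 and 0.0837, drug metabolism 0.0631 and 0.0632, immediate early 0.0601 and 0.0608, and neutrophil 0.116 and 0.117. With the filter of 5 FPKM the bile acid synthesis, drug metabolism, immediate early and neutrophil lists had 0.0535, 0.0535, 0.0535 and 0.151, and without both untreated libraries numbered 1 they had 0.107, 0.107, 0.107 and 0.134. With no filter bile acid synthesis, drug metabolism and neutrophil had 0.0565, 0.179 and 0.0581. With quantile normalization bile acid synthesis and neutrophil had 0.127 and 0.0565, and with a pseudocount of 0.1 neutrophil had 0.158. The number of lists called was 5 without either of these untreated libraries and 15 without replicate 2 of wild type with LPS.

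Across genes the transgene differences in untreated and LPS-treated mice had Pearson r = -0.08 and Spearman rho = -0.17, and Pearson r was 0.11 without replicate 2 of untreated wild type. The fifth comparison, the interaction, asked whether the LPS change differed between genotypes. Mup12 passed (adjusted p = 0.0422) and was named after its values were seen, and 1189 genes had an unadjusted p under 0.05. Mup12 stood at 64.0 ± 36.6 FPKM in untreated transgenic liver (SD, n = 2), 0.747 ± 0.635 FPKM in transgenic liver with LPS and 2.21 ± 0.778 FPKM in wild-type liver with LPS, and was listed at 0 in untreated wild type. Near misses were Fam107a (3.22, adjusted p = 0.0793), the stress gene Gadd45b (2.76, adjusted p = 0.0793), the Kansl2 row (-2.44, adjusted p = 0.0896), Upp2 (2.06, adjusted p = 0.11) and Acacb (1.86, adjusted p = 0.13). The count of 1 was 0 without any 1 of the 4 wild-type libraries, 4 without either untreated transgenic library and 276 without replicate 2 of transgenic with LPS. With replicate 1 of that group left out the 1 gene was not Mup12. It was also 0 with no filter, quantile normalization, median-of-ratios scaling, robust moderation or without both untreated libraries numbered 1, and 2 with the replicate block. Camera called 8 lists for the interaction, led by glucose metabolism (median 0.64, adjusted p = 1.55e-05, adjusted p = 0.32 with an estimated correlation) and female-biased genes (1.42, adjusted p = 6.79e-05, adjusted p = 0.251 with an estimated correlation). The other 20 had adjusted p from 0.102 (pancreas and adipose) to 0.881 (bile acid synthesis, circadian clock and lipoprotein transport).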

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

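The interaction tests below were planned, the choice of Mup12 and the tests of a wrong label and of a lower hepatocyte share were made only after the results were seen, and the test of food intake was written before its values were seen but after Igfbp1 and Ddit4 had been noticed. The results in this part are given because they passed the interaction test, by camera for the lists and by limma for Mup12.

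Camera called 8 lists. The LPS change was higher in transgenic mice for acute phase (median interaction 0.61, adjusted p = 0.000303), female-biased (1.42, adjusted p = 6.79e-05), glucose metabolism (0.64, adjusted p = 1.55e-05) and immediate early and heat shock genes (0.53, adjusted p = 0.0136). It was lower for B and plasma cell (-0.59, adjusted p = 0.000722), cholesterol synthesis (-1.17, adjusted p = 0.000722), interferon-stimulated (-0.42, adjusted p = 0.0105) and male-biased genes (-0.57, adjusted p = 0.0301). None of the 8 was called with an estimated correlation (adjusted p = 0.251 to 0.934 with an estimated correlation). By fry the unadjusted p was 0.0112 for female-biased, 0.0228 for glucose metabolism and 0.0351 for B and plasma cell genes. By the same test it was 0.179 for acute phase, 0.193 for interferon-stimulated, 0.356 for cholesterol synthesis, 0.414 for male-biased and 0.589 for immediate early genes.

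The acute phase, female-biased and glucose metabolism lists kept their calls in every refit without 1 library. Without replicate 1 of transgenic with LPS the cholesterol, immediate early and male-biased lists had adjusted p of 0.27, 0.315 and 0.433, and without replicate 2 of that group the B cell list had 0.0901. The cholesterol median was -0.24 without that replicate 1 and -2.23 without replicate 2, where 16 of its genes passed as lower, against 0 in limma with all libraries (1189 of all genes at an unadjusted p under 0.05). Without replicate 1 of untreated wild type the immediate early and male-biased lists had 0.641 and 0.941, without replicate 2 of untreated wild type the interferon list had 0.0554, without replicate 1 of untreated transgenic it had 0.11, without replicate 2 of untreated transgenic the immediate early and male-biased lists had 0.177 and 0.404, and without replicate 1 of wild type with LPS the male-biased list had 0.0658. The immediate early list had 0.0623 with the filter of 5 FPKM, and without both untreated libraries numbered 1 the B cell, cholesterol, immediate early and male-biased lists had 0.117, 0.117, 0.518 and 0.518.

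Mup12 had a fitted interaction of -6.80 (SE 0.58, adjusted p = 0.0422), which is no fold because the gene is listed at 0 in both untreated wild-type libraries. Its call ended without any 1 of the 4 wild-type libraries or without replicate 1 of transgenic with LPS (refit range -7.41 to -6.20). Reads shared between near-identical major urinary protein genes were not tested as an explanation.

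The cholesterol value rests on transgenic mice with LPS, whose replicate 1 stood apart from replicate 2, with Hmgcs1 at 24.6 and 268 FPKM. Toward a wild-type library under a wrong label, 22 genes outside the cholesterol list placed replicate 1 near wild type (median position 0.021, quartiles -0.138 and 0.907, 7 genes above 0.5, where 0 is wild type and 1 transgenic), as did 21 cholesterol genes (0.228), while each of the other 7 libraries held out in the same way had a median of 0.719 to 1.10 toward its own genotype. Only members of the cholesterol list were left out of the 22 genes, so other genes that vary with that list can be among them. Fasn, a lipogenesis gene chosen after its values were seen, was 1.88 higher on the log2 scale in untreated transgenic mice. Under LPS it was 1.90 higher with replicate 1 left out, and stood at 29.8 ± 25.7 FPKM over both replicates. The 22 genes may therefore partly restate the low cholesterol values of replicate 1. Against a wrong label, Cyp7a1 placed the library with the transgenic ones (1.04), and 14 of 23 cholesterol genes lay above all 4 wild-type libraries. In Cyp2c38, named for its call in untreated mice, both replicates of transgenic with LPS were alike and apart from both wild-type LPS libraries (7.14 and 8.17 against 12.6 and 12.8 FPKM). The same held for Snhg9 (1.86 and 2.00 against 7.48 and 7.42 FPKM) and Adora1 (4.48 and 4.08 against 12.3 and 10.9 FPKM). Snhg9 and Adora1 were among the smallest p for the transgene under LPS, a contrast that includes this library. The call of Cyp2c38 came from a fit whose variance per gene also includes this library. Such choices favor genes in which both replicates of transgenic with LPS are alike. Cyp2c38, Snhg9 and Adora1 therefore do not count against a wrong label. The library and a mislabelled one cannot be told apart from the other values, which point both ways. A lower share of hepatocytes would raise the markers of the other 4 cell types alike, while the medians were 0.034 for macrophage, 0.022 for endothelial and 0.135 for stellate cells (upper bounds 0.217, 0.125 and 0.191, under the 0.3 that was asked for after the medians were seen), against 0.587 for cholangiocytes (-0.293 to 0.726) and -0.15 for hepatocytes. Also open is food intake or stress hormone state at collection, which may contribute. A set of 11 genes raised by fasting or glucocorticoids was higher in replicate 1 by a median of 0.291, with 7 of 11 genes higher. Not higher than in replicate 2 were Fkbp5 (91.7 against 126.1 FPKM), Tsc22d3 (116.1 against 116.6 FPKM), Klf9 (39.4 against 48.3 FPKM) and Bcl6 (2.84 against 10.6 FPKM). The median lay above the 95th percentile of random lists at 0.069, whose genes need not vary together as these do. The 11 genes also differed by a median of 0.491 between both untreated transgenic replicates, and no biological explanation from the design was tested.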

How the results depend on the processing

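Leaving out pancreas-following features, leaving out both untreated libraries numbered 1 and counting shared values in a list by any name were chosen after seeing the data, and the other settings were planned. Causes were not tested.

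With a filter of 5 FPKM 1379 genes passed for LPS in wild type and 1835 in transgenic mice. With no filter the counts were 0 for the transgene in untreated mice, 1 in LPS and 0 for the interaction. With quantile normalization they were 1 for the transgene in LPS and 0 for the interaction, which also gave 0 with median-of-ratios scaling and with robust moderation, and 2 with the replicate number as a block. The correlation of replicate deviations between groups, which the block assumes, lay between 0.043 and 0.459. With only the 2 groups compared 22 genes passed for the transgene in untreated mice, a setting that was not run for the interaction or the lists. With an estimated correlation camera called 0 lists in each of the 5 contrasts, where the smallest adjusted p was 0.236, 0.253, 0.302, 0.706 and 0.251.

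Without both untreated libraries numbered 1, 1669 genes passed for LPS in transgenic mice, 0 for the transgene in untreated mice and 0 for the interaction, 5 lists passed for the transgene in LPS and 5 for the interaction, and the correlations across genes were 0.698 for LPS and -0.198 for the transgene. Without the pancreas-following features the counts were 2501, 3021, 7, 0 and 1.

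Without 1 library at a time, the lone library of the group was assumed to vary like the other groups. The counts of genes ranged from 1219 to 3453 for LPS in wild type, 1233 to 3641 in transgenic mice, 2 to 44 for the transgene in untreated mice, 0 to 423 in LPS and 0 to 276 for the interaction. The lists called ranged from 15 to 20, 18 to 22, 7 to 14, 5 to 15 and 7 to 12. The correlation for LPS ranged from 0.650 to 0.779, and that for the transgene from -0.211 to 0.112, the last without replicate 2 of untreated wild type.

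For 3 lists the direction given by camera turned over, though the median kept its sign. These were pancreas and adipose for the transgene in untreated mice (median 0.58 without replicate 2 of untreated wild type, refit range 0.58 to 4.46), neutrophil for the transgene in LPS (-0.0485 without replicate 2 of transgenic with LPS, range -0.70 to -0.0485) and male-biased for the interaction (-0.17 without replicate 1 of untreated wild type, range -0.99 to -0.17). In the counts that follow, a called gene or list is the same if it kept its call and direction. A gene that did not pass in the reported fit is the same if it moved by less than its SE. The count for named genes therefore includes genes that had no call to lose. Over all settings, values of named genes were the same in 6862 cases, lost the call in 459, gained it in 77 and, without a test, moved in 215, and those of lists were the same in 1056 and lost the call in 160.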

Other observations

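All tests in this part were chosen only after the results were seen, apart from the list tests. Pancreatic enzyme genes moved together across the libraries, with a mean log2 level of 9 acinar genes at 6.88 and 3.09 in untreated wild type, 4.12 and 2.76 in wild type with LPS, 8.88 and 6.69 in untreated transgenic and 3.67 and 0.85 in transgenic with LPS. In wild type the lower untreated library lay below the higher LPS library (difference -1.03), and in transgenic mice both untreated libraries lay above both LPS libraries, by 3.01. With 2 libraries per group an effect of LPS and a chance difference in carried tissue cannot be told apart in either genotype. Pancreas tissue carried with the liver piece is a candidate explanation, since the genes kept nearly 1 ratio to each other (median residual SD 0.26 on the log2 scale in 7 libraries, over which the level ranged by 6.12, with the lowest library left out) and 10 acinar genes outside the list followed them with a median r of 0.993. Of the 76 features that follow these genes, 42 were called lower with LPS in transgenic mice.

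Markers of macrophages, liver endothelial cells and stellate cells were higher after LPS in both genotypes, and cholangiocyte markers were not called (medians 0.39 and -0.09). The 3 calls were lost with an estimated correlation (adjusted p = 0.236 in wild type and 0.253 in transgenic mice). A lower share of hepatocytes as the whole cause is excluded, because it would raise the markers of all other cells alike, while the macrophage median exceeded the cholangiocyte median by 2.18 in wild type (permutation p = 0.00018) and by 2.58 in transgenic mice (permutation p = 3e-05, with genes of a list not independent). More macrophages, or more transcript per macrophage, stay open and may both contribute to the 2.18, since whole liver RNA holds no cell counts.

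In untreated wild type, Adipoq and Cfd, both adipose genes, stood at 4.83 and 24.7 FPKM in replicate 1 and at 0.327 and 1.22 FPKM in replicate 2. In the same group the keratin genes Krt13 and Krt4 were listed at 0 in replicate 1 and stood at 16.6 and 13.0 FPKM in replicate 2. No explanation was tested for these genes.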
